A study of Homo sapiens with 18 samples.

How the data were processed

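Per the labels, H1299 cells were seeded through the trachea of decellularized rat lungs that were perfused with medium, CTC were collected from the medium, and tumour and lesions were isolated on the days named. RNA was labelled with Cy5 and hybridised to human OneArray slides, 1 array per sample, 18 arrays in 6 groups of 3. The deposited values are an intensity per probe on a linear scale, from -0.70 to 65578, for 31741 probes. The scanner, the background correction and the normalization are not given in the sources used here. From the values, the 18 arrays had equal 5th, 25th, 50th, 75th and 95th percentiles, as normalization between arrays gives, while the 99.5th percentile ran from 27662 to 42761, with at most 30102 on day 10 lesion arrays and at least 31227 on the others. No detection calls were used, so a dim probe has no stated bound. No pair of arrays was identical.

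Values under 1 were raised to 1 and taken to log2. The 30% of probes with the lowest mean (log2 4.28, an intensity of 19.4) were not tested, which left 22218. Probes were named from the platform annotation, in which 24740 probes have 1 symbol, 977 several and 6024 none. Of 18365 symbols, 16811 are current in the RefSeq gene table of GRCh38.p14, 1497 matched through a synonym and 57 did not match. Human genes were read on a culture whose scaffold is from rat. No coordinates are given.

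Limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group on all 18 arrays (12 residual and 4.35 prior degrees of freedom, prior variance with a trend), with two-sided tests and Benjamini-Hochberg adjustment over tested probes at 0.05. An exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so limma, which pools the spread over groups and probes, was used. The 9 contrasts were 7 pairwise comparisons, the lesion against CTC difference averaged over both days, and its change between days. For each of 29 gene lists, camera with a preset correlation of 0.01 compared its genes (1 probe per gene, the brightest of 14061) with all others, adjusted over the lists of a contrast, and was repeated with an estimated correlation. Of 59 calls, 3 held then. Fry tests whether genes of a list move on balance 1 way and does not compare them with other genes.

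Genes were named by a rule: per direction the 12 (day 25 comparisons and the average) or 6 largest changes among called probes with 1 symbol whose groups did not overlap, a property that chance gives 10% of probes, and up to 4 members with the smallest p per list. From these, the comparisons give genes whose call held in every leave-one-out fit and alternative that tested them, a selection made after the data were seen. Genes named as dark probes, and those listed for the change between days, were not selected in this way. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other filters on dim probes, quantile normalization, median centring, no trend, array weights, a replicate block, an offset of 50, only the arrays compared, other list tests, and leaving out each array.

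A probe was called dark where it read under 8 on at least 1 array with a median over 100, which held for 91 tested probes. Array background was the median of 293 olfactory receptor probes. The fit was tested on simulated data for CTC against primary tumour at day 25 over 22218 probes: it recovered 14 of 67 probes changed 1.5-fold (20.9%), 51 of 67 changed 2-fold (76.1%) and 64 of 66 changed 4-fold (97.0%), with 5 false calls, and made 0 calls without change. Noise was drawn independently for each probe and array. Shifts shared by the probes of an array were not simulated, so false calls from them are not covered.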

Results

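H1299, an established human non-small cell lung cancer line, was grown in decellularized rat lungs perfused with medium, a culture in which cells seeded through the trachea form a primary tumour, shed cells into the medium, and seed lesions in other lobes. RNA from 6 groups was hybridised to 1-colour human arrays: primary tumour of days 2 and 25, circulating tumour cells (CTC) collected from the medium on days 10 and 25, and metastatic lesions of days 10 and 25. Each group held 3 arrays, named in the labels as biological replicates, and the number of arrays limits the precision. The labels do not say whether the 3 came from separate models, so p-values measure the spread between these samples. Every array had the same median intensity (68.3), and correlations between replicates ran from 0.966 to 0.995.

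Lesions of day 10 stood apart from every other group. On the first principal component, which held 43.9% of the variance over 22218 tested probes, their arrays lay between -119 and -90.3, while primary tumours of day 2 lay between -25.4 and -0.0171 and the other 12 arrays lay between 5.33 and 46.0. Limma found differences among the 6 groups at 18607 probes (83.7% of those tested). The day 10 lesion arrays also differed in signal: between 49 and 54 probes that were bright on most arrays read close to 0 there, against at most 5 on any other array. The median log2 intensity of probes for olfactory receptors, genes read mainly in the nose, was 4.17 to 4.30 there, above CTC of day 10 (3.89 to 4.00) but within the range of all other arrays (3.77 to 4.39). Lesions of day 25 differed among themselves: replicate 2 lay at 19.2 on the second component, near primary tumour of day 25 (4.57 to 19.9), and replicates 1 and 3 at 62.8 and 47.1. Their olfactory receptor medians were split alike: 3.95 on replicate 2, within primary tumour of day 25 (3.93 to 4.09), and 4.39 and 4.34 on replicates 1 and 3. Likeness to the tumour and array background cannot be told apart here.

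**Figure D1:**
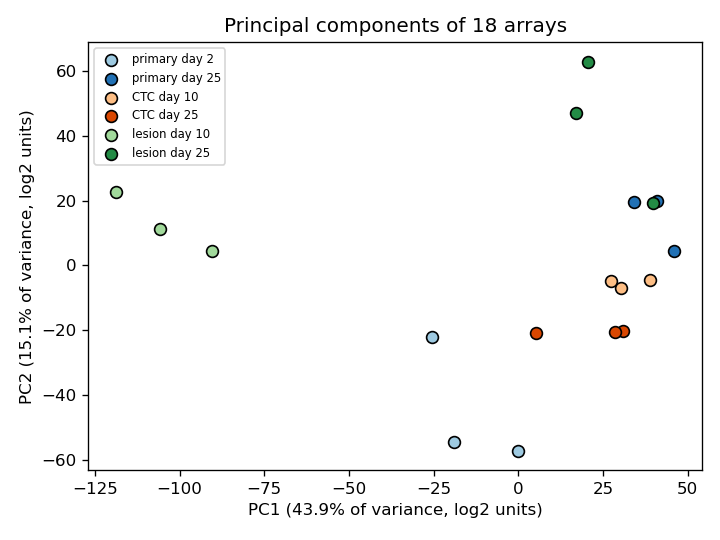
First and second principal components of log2 intensity over the 22218 tested probes, 1 point per array and 1 colour per group (n = 3 arrays each), with the share of variance on each axis (43.9% and 15.1%). The 3 arrays of day 10 lesions lie between -119 and -90.3 on the first component, and all others lie at -25.4 or above.

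Shed cells were compared with the primary tumour of the same day: 16 of 24 hypoxia response and 5 of 19 matrix genes were lower in CTC, 12 of 36 cell cycle genes were higher, and of 22 immediate early genes 5 were higher and 2 lower. These list calls were lost with an estimated correlation (adjusted p = 0.249 for hypoxia response and 0.268 for the others). SLC2A3, a glucose transporter, was lower in CTC of day 25 than in primary tumour of day 25 (log2 fold change -2.18, SE 0.27, adjusted p = 1.69e-04), as was HK2, which catalyses the first step of glycolysis (log2 fold change -1.65, SE 0.25, adjusted p = 6.16e-04). FOS, a transcription factor induced within minutes of stimulation, was higher (log2 fold change 2.36, SE 0.21, adjusted p = 2.49e-05). Mean log2 intensities of MMP7, a secreted protease, were 7.82 ± 0.34 against 10.34 ± 0.63 (SD, n = 3 each), a fall of 5.71-fold, and those of LUM, which encodes the matrix proteoglycan lumican, were 6.67 ± 0.12 against 8.94 ± 0.22.

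In the hypoxia response list 0 of 24 measured members rose, 16 fell and 8 did not pass (1 up and 19 down adjusted over the list alone). Hypoxia response genes had a median log2 fold change of -0.94 (adjusted p = 1.69e-10, and adjusted p = 0.249 with an estimated correlation). KDM4B (-1.18) and PFKFB4 (-1.57) had log2 fold changes in that direction as well. Among glycolysis genes 0 of 16 measured members rose, 6 fell and 10 did not pass (0 up and 6 down adjusted over the list alone). Glycolysis had a median log2 fold change of -0.30 (adjusted p = 0.0104, and adjusted p = 0.268 with an estimated correlation), led by HK2 and ALDOC, whose log2 fold change was -1.12. With array weights that call ended (adjusted p = 0.0834), and its median was -0.196 under quantile normalization and -0.167 without CTC day 25 replicate 3. For extracellular matrix 0 of 19 measured members rose, 5 fell and 14 did not pass (1 up and 7 down adjusted over the list alone). Matrix genes had a median log2 fold change of -0.39 (adjusted p = 0.00569, and adjusted p = 0.268 with an estimated correlation). Its leading members were LAMA4, a laminin chain, with a log2 fold change of -2.15 from a CTC mean (4.33) close to the level of the dim filter (-0.99 with an offset), and FBN1, or fibrillin 1, with -1.03. In the interferon response 0 of 17 measured members rose, 5 fell and 12 did not pass (0 up and 7 down adjusted over the list alone). Interferon response had a median log2 fold change of -0.32 (adjusted p = 4.87e-04, and adjusted p = 0.249 with an estimated correlation), and IFITM1 had a log2 fold change of -1.93.

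In the cell cycle list 12 of 36 measured members rose, 0 fell and 24 did not pass (15 up and 0 down adjusted over the list alone). Cell cycle genes had a median log2 fold change of 0.32 (adjusted p = 2.32e-06, and adjusted p = 0.268 with an estimated correlation). The members with the smallest p were genes of DNA replication and its onset, with log2 fold changes of 0.96 for MCM4, 0.97 for PCNA, 1.17 for CCNE2 and 1.07 for CDC6. Among immediate early genes 5 of 22 measured members rose, 2 fell and 15 did not pass (7 up and 2 down adjusted over the list alone). Immediate early genes had a median log2 fold change of 0.38 (adjusted p = 0.00863, and adjusted p = 0.268 with an estimated correlation), and FOSB had a log2 fold change of 1.71. For the heat shock response 2 of 13 measured members rose, 0 fell and 11 did not pass (3 up and 0 down adjusted over the list alone). Heat shock response had a median log2 fold change of 0.22 (adjusted p = 0.0243, and adjusted p = 0.249 with an estimated correlation). That call ended without primary tumour day 25 replicate 1 (adjusted p = 0.0543), CTC day 25 replicate 1 (0.0630) or replicate 2 (0.0522), and with array background as a covariate (0.0776).

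Over all probes, 1716 rose and 1509 fell in CTC, 3225 in all, of which 309 rose and 254 fell by over 2-fold. Other large differences were RN7SK, a small nuclear RNA (log2 fold change 3.20, SE 0.35, adjusted p = 7.47e-05), CYR61, now CCN1, a secreted matrix-associated protein (log2 fold change 2.07, SE 0.29, adjusted p = 3.42e-04), MGP, or matrix Gla protein (log2 fold change -3.38, SE 0.57, adjusted p = 0.00119), and SERPINF1 (log2 fold change -2.23, SE 0.30, adjusted p = 2.85e-04), whose log2 fold change was -1.36 with an offset. The count was 9186 with array weights. It fell to 1854, 1804 and 2042 without primary tumour day 25 replicates 1, 2 and 3, and to 1784 without CTC day 25 replicate 3.

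Metastatic lesions were compared with primary tumour on the same day: 9 of 19 matrix, 10 of 23 matrix proteolysis and 9 of 22 immediate early genes were lower in lesions, and 1, 3 and 1 were higher. The 3 list calls were lost with an estimated correlation (adjusted p = 0.366, 0.357 and 0.357). MMP7 had mean log2 intensities of 5.08 ± 0.93 against 10.34 ± 0.63 (SD, n = 3 each) in lesions and primary tumour (log2 fold change -5.26, SE 0.43, adjusted p = 3.88e-06). LOX, which cross-links collagen, was lower (log2 fold change -2.80, SE 0.24, adjusted p = 3.90e-06), as were COL1A1, a collagen I chain (log2 fold change -2.37, SE 0.26, adjusted p = 2.59e-05), and PRDM1, a transcriptional repressor (log2 fold change -2.58, SE 0.25, adjusted p = 9.46e-06). In lesions MMP7 was at the level of the dim filter (log2 4.28) on replicate 1, and PRDM1 had a mean close to it (4.38 ± 0.48), so the sizes of both differences depend on background (-1.29 for PRDM1 with an offset). TM4SF1, a surface protein of the tetraspanin-like family, was higher (log2 fold change 1.92, SE 0.28, adjusted p = 2.44e-04).

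For matrix proteolysis 3 of 23 measured members rose, 10 fell and 10 did not pass (3 up and 13 down adjusted over the list alone). Matrix proteolysis had a median log2 fold change of -0.46 (adjusted p = 0.00717, and adjusted p = 0.357 with an estimated correlation), and TIMP2, an inhibitor of matrix proteases, had a log2 fold change of -1.44, against -1.61 for MMP10 and -1.27 for PLAUR. In the extracellular matrix list 1 of 19 measured members rose, 9 fell and 9 did not pass (2 up and 10 down adjusted over the list alone). The median over matrix genes was -0.55 (adjusted p = 0.0123, and adjusted p = 0.366 with an estimated correlation), with log2 fold changes of -1.68 for COL12A1 and -1.15 for COL6A2. That call ended with a stricter filter on dim probes, where the median was -0.244 (adjusted p = 0.105). Among immediate early genes 1 of 22 measured members rose, 9 fell and 12 did not pass (2 up and 10 down adjusted over the list alone). The median over immediate early genes was -0.32 (adjusted p = 0.00717, and adjusted p = 0.357 with an estimated correlation), with log2 fold changes of -1.31 for JUN, -1.30 for IER3 and -1.42 for ZFP36. Without metastatic lesion day 25 replicate 3 the adjusted p of that list was 0.0868, and its median was -0.489 without replicate 2 and -0.582 with a stricter filter on dim probes.

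Hypoxia response and cell cycle lists were not called between these solid samples: in the first 5 rose and 4 fell of 24 (adjusted p = 0.786), and in the second 5 rose and 4 fell of 36 (adjusted p = 0.862). In all, 2040 probes rose and 3070 fell in lesions. The 5110 calls became 10342 with array weights and 1935 with only the 6 arrays compared, 3364 without primary tumour day 25 replicate 1 and 3143 without metastatic lesion day 25 replicate 1.

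Against CTC of the same day, 17 of 24 hypoxia response genes were higher in lesions of day 25 and 2 lower, 17 of 36 cell cycle genes were lower and 3 higher, and 15 of 22 immediate early genes were lower and 1 higher. The 3 list calls were lost with an estimated correlation (adjusted p = 0.508, 0.508 and 0.147). HK2 was higher in lesions (log2 fold change 2.18, SE 0.25, adjusted p = 3.40e-05), as were ANKRD37, a hypoxia-induced gene (log2 fold change 2.52, SE 0.35, adjusted p = 1.31e-04), and ERO1L, now ERO1A, an oxidase of the endoplasmic reticulum (log2 fold change 2.37, SE 0.33, adjusted p = 1.18e-04). JUN, a partner of FOS, was lower (log2 fold change -1.80, SE 0.09, adjusted p = 2.82e-08), as were FOS (log2 fold change -2.31, SE 0.21, adjusted p = 1.06e-05), COL1A1 (log2 fold change -2.31, SE 0.26, adjusted p = 3.06e-05) and THBS1, or thrombospondin 1 (log2 fold change -2.45, SE 0.32, adjusted p = 8.11e-05), at -1.58 with array background as a covariate.

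In the hypoxia response list 17 of 24 measured members rose, 2 fell and 5 did not pass (18 up and 2 down adjusted over the list alone). The median over hypoxia response genes was 0.95 (adjusted p = 1.04e-06, and adjusted p = 0.508 with an estimated correlation), with log2 fold changes of 1.55 for KDM3A, 1.62 for BNIP3L and 1.56 for NDRG1. In the cell cycle list 3 of 36 measured members rose, 17 fell and 16 did not pass (3 up and 20 down adjusted over the list alone). The median over cell cycle genes was -0.42 (adjusted p = 0.00187, and adjusted p = 0.508 with an estimated correlation), with -1.42 for MCM5, -1.35 for CDC6 and -1.34 for CCNE1. That median was -0.639 with array weights and -0.275 without metastatic lesion day 25 replicate 1. Among immediate early genes 1 of 22 measured members rose, 15 fell and 6 did not pass (1 up and 15 down adjusted over the list alone). Over immediate early genes the median was -0.83 (adjusted p = 1.04e-06, and adjusted p = 0.147 with an estimated correlation), with -1.34 for KLF6 and -1.45 for DUSP1.

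For integrins and focal adhesion 2 of 23 measured members rose, 10 fell and 11 did not pass (3 up and 13 down adjusted over the list alone). Integrins and focal adhesion had a median log2 fold change of -0.43 (adjusted p = 0.0377, and adjusted p = 0.508 with an estimated correlation), with log2 fold changes of -0.97 for ITGB5 and -0.99 for ACTN4. That call ended without CTC day 25 replicate 2 (adjusted p = 0.0692), metastatic lesion day 25 replicate 1 (0.0932) or replicate 3 (0.137), with array background as a covariate (0.302), without a filter on dim probes (0.0707) and without a trend (0.0606). The mean level of that list on metastatic lesion day 25 replicate 2 was 0.115, nearer to CTC (0.16 to 0.24) than to replicates 1 (-0.262) and 3 (-0.299). Among ribosomal proteins 9 of 23 measured members rose, 2 fell and 12 did not pass (10 up and 2 down adjusted over the list alone). Ribosomal proteins had a median log2 fold change of 0.25 (adjusted p = 0.0377, and adjusted p = 0.508 with an estimated correlation), with 0.94 for RPL15 and -1.16 for RPS10. That call ended without CTC day 25 replicate 3 (median 0.162, adjusted p = 0.152), metastatic lesion day 25 replicate 1 (0.0932) or replicate 2 (0.0778), under quantile normalization (0.0701), without a filter on dim probes (0.0707), without a trend (0.0822) and with array background as a covariate (0.0804).

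Here 3292 probes rose and 4105 fell in lesions. The 7397 calls became 13386 with array weights, 3131 with only the 6 arrays compared, 3826 with array background as a covariate and 4472 without metastatic lesion day 25 replicate 1.

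CTC of day 25 stood on the same side of both solid samples at 1652 probes, of which 1089 were higher in CTC and 563 lower. Independent lists would share 317 and 224. Simulated groups without effects gave 0 on average over 50 draws, but hardly any probe is called there, so that count says nothing of the shared CTC arrays. The fold changes of CTC against either solid sample correlated across probes, which are not independent replicates, at 0.537 against 0.498 simulated, with a covariance of 0.131 against 0.0263 simulated. Part of the excess may come from the shared CTC arrays. The count was 5483 with array weights (2939 higher and 2544 lower), 1045 with only the arrays of day 25 and 1023 with array background as a covariate. It was 1054 without primary tumour day 25 replicate 1, 1013 without replicate 2 and 892 without CTC day 25 replicate 3. With lesions of day 25 in the place of CTC the count was 3038, so CTC were not the group most apart by this measure.

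**Figure D2:**
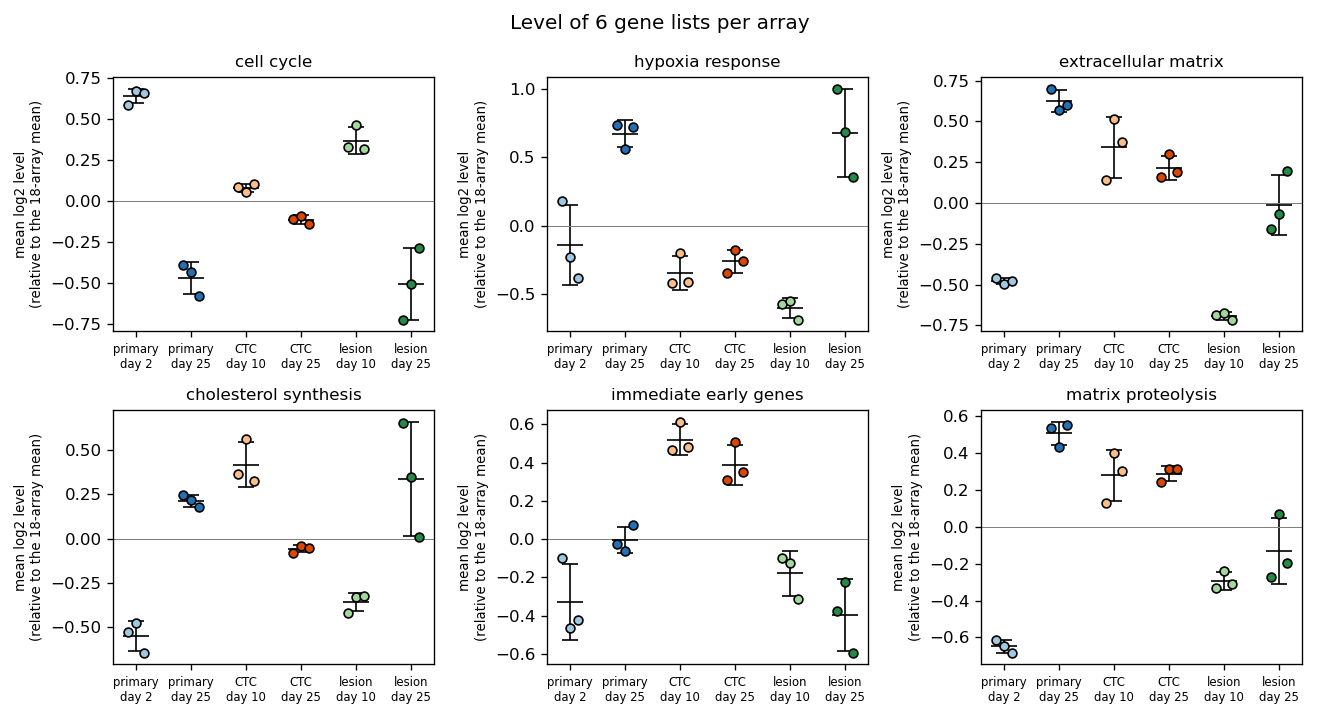
Mean log2 level of 6 gene lists relative to the mean of all arrays, 1 point per array and a bar at the group mean with its SD (n = 3). Hypoxia response genes stood at 0.67 ± 0.10 in primary tumour and 0.68 ± 0.32 in lesions of day 25, against -0.26 ± 0.08 in CTC.

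Between days 2 and 25 in primary tumours, 34 of 36 cell cycle genes fell, 14 of 23 matrix proteolysis genes rose and 1 fell, 9 of 18 mesenchymal genes rose and 1 fell, and 14 of 19 matrix genes rose. The matrix call was lost with an estimated correlation (adjusted p = 0.0557), and the others held (adjusted p = 0.0462 each). FN1, or fibronectin, rose (log2 fold change 4.68, SE 0.21, adjusted p = 1.89e-09), with mean log2 intensities of 15.03 ± 0.26 against 10.34 ± 0.09 on day 25 against day 2 (SD, n = 3 each). COL1A1 rose (log2 fold change 2.82, SE 0.26, adjusted p = 6.22e-07), as did TGFBI, a secreted matrix protein (log2 fold change 2.88, SE 0.19, adjusted p = 3.91e-08). CDC6, which licenses DNA replication, fell (log2 fold change -2.18, SE 0.17, adjusted p = 1.49e-07), as did CCNA2, or cyclin A2 (log2 fold change -1.59, SE 0.13, adjusted p = 1.57e-07). MMP7 rose by a log2 fold change of 7.53 and MGP by 7.28, both from day 2 levels under the level of the dim filter, where fold sizes depend on background (4.56 and 3.97 with an offset).

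In the cell cycle list 0 of 36 measured members rose, 34 fell and 2 did not pass (0 up and 36 down adjusted over the list alone). Over cell cycle genes the median was -1.05 (adjusted p = 2.08e-16, and adjusted p = 0.0462 with an estimated correlation), and RRM2, a subunit of the enzyme that makes deoxyribonucleotides, had a log2 fold change of -1.74. In the matrix proteolysis list 14 of 23 measured members rose, 1 fell and 8 did not pass (15 up and 1 down adjusted over the list alone). The median over matrix proteolysis was 0.68 (adjusted p = 5.85e-06, and adjusted p = 0.0462 with an estimated correlation), with log2 fold changes of 2.60 for TIMP2, 1.89 for MMP1 and 1.84 for CTSB. In the mesenchymal list 9 of 18 measured members rose, 1 fell and 8 did not pass (9 up and 1 down adjusted over the list alone). Mesenchymal state had a median log2 fold change of 0.53 (adjusted p = 2.44e-04, and adjusted p = 0.0462 with an estimated correlation), with 2.22 for S100A4 and 0.92 for SPARC. These 3 calls were the ones, over all comparisons, that held with an estimated correlation. For extracellular matrix 14 of 19 measured members rose, 0 fell and 5 did not pass (14 up and 0 down adjusted over the list alone). Over matrix genes the median was 1.22 (adjusted p = 1.94e-06, and adjusted p = 0.0557 with an estimated correlation), with 2.35 for FBN1 and 1.44 for LAMB1.

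In the hypoxia response list 14 of 24 measured members rose, 0 fell and 10 did not pass (15 up and 0 down adjusted over the list alone). Over hypoxia response genes the median was 0.86 (adjusted p = 8.75e-05, and adjusted p = 0.263 with an estimated correlation), with log2 fold changes of 1.80 for LOX and 1.73 for P4HA2, an enzyme that modifies collagen. For cholesterol synthesis 11 of 18 measured members rose, 0 fell and 7 did not pass (12 up and 2 down adjusted over the list alone). Cholesterol synthesis had a median log2 fold change of 0.74 (adjusted p = 2.44e-04, and adjusted p = 0.177 with an estimated correlation), with 1.99 for INSIG1 and 1.21 for DHCR7. For fatty acid synthesis and lipid storage 9 of 16 measured members rose, 3 fell and 4 did not pass (9 up and 3 down adjusted over the list alone). Fatty acid synthesis and lipid storage had a median log2 fold change of 0.37 (adjusted p = 0.0371, and adjusted p = 0.165 with an estimated correlation), with 2.15 for SCD and 1.24 for FASN. For the interferon response 8 of 17 measured members rose, 0 fell and 9 did not pass (10 up and 0 down adjusted over the list alone). The median over interferon response was 0.47 (adjusted p = 0.0107, and adjusted p = 0.219 with an estimated correlation), with 2.95 for IFITM1. Among immediate early genes 8 of 22 measured members rose, 2 fell and 12 did not pass (8 up and 2 down adjusted over the list alone). Immediate early genes had a median log2 fold change of 0.31 (adjusted p = 0.0239, and adjusted p = 0.263 with an estimated correlation), with 1.95 for JUND.

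For angiogenic and growth factors 11 of 17 measured members rose, 3 fell and 3 did not pass (11 up and 3 down adjusted over the list alone). Angiogenic and growth factors had a median log2 fold change of 0.69 (adjusted p = 0.0135, and adjusted p = 0.0557 with an estimated correlation), with log2 fold changes of 1.43 for VEGFC and -1.66 for NRG1. For autophagy and lysosome 11 of 22 measured members rose, 3 fell and 8 did not pass (12 up and 3 down adjusted over the list alone). Autophagy and lysosome had a median log2 fold change of 0.42 (adjusted p = 0.0304, and adjusted p = 0.108 with an estimated correlation), where SQSTM1, an autophagy receptor, had -1.91 and HEXA, a lysosomal enzyme, 1.19. For growth factor receptors and signalling 7 of 20 measured members rose, 1 fell and 12 did not pass (7 up and 1 down adjusted over the list alone). Growth factor receptors and signalling had a median log2 fold change of 0.19 (adjusted p = 0.0364, and adjusted p = 0.108 with an estimated correlation), with 1.53 for SPRY2. Among fibroblast and smooth muscle markers 5 of 9 measured members rose, 2 fell and 2 did not pass (5 up and 2 down adjusted over the list alone). Fibroblast and smooth muscle markers had a median log2 fold change of 0.61 (adjusted p = 0.0371, and adjusted p = 0.165 with an estimated correlation). Collagen chains of that list are also in the matrix list. For oxidative phosphorylation 1 of 18 measured members rose, 7 fell and 10 did not pass (1 up and 8 down adjusted over the list alone). Oxidative phosphorylation had a median log2 fold change of -0.25 (adjusted p = 0.0371, and adjusted p = 0.263 with an estimated correlation), with -1.50 for NDUFA9.

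In all, 3936 probes rose and 4125 fell, 8061 together. The oxidative phosphorylation call ended without primary tumour day 2 replicate 2 (adjusted p = 0.0921), day 25 replicate 1 (0.0509) or replicate 3 (0.0582), that of fatty acid synthesis without day 2 replicate 2 (0.0502) or day 25 replicate 1 (0.0506), and that of fibroblast markers without day 2 replicate 2 (0.0511). Calls also ended for fatty acid synthesis with the mean over the probes of a gene (adjusted p = 0.104), for fibroblast markers with array weights (0.0715) and an offset (0.0575, with a median of 0.212), for oxidative phosphorylation with a stricter filter on dim probes (0.0513), and for growth factor receptors with dark probes left out (0.0570). With a stricter filter on dim probes the medians were 1.02 for matrix proteolysis, 0.586 for immediate early genes and 3.26 for fibroblast markers, and with an offset that of angiogenic and growth factors was 0.413.

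Between days 10 and 25 in CTC, 6 of 16 genes of fatty acid synthesis and lipid storage and 6 of 18 of cholesterol synthesis fell, and the others did not pass. Both list calls were lost with an estimated correlation (adjusted p = 0.149 and 0.417). FASN, or fatty acid synthase, fell (log2 fold change -1.30, SE 0.11, adjusted p = 2.42e-05), as did HMGCS1 (log2 fold change -1.90, SE 0.28, adjusted p = 4.94e-04) and LSS (log2 fold change -1.07, SE 0.15, adjusted p = 3.94e-04), enzymes of cholesterol synthesis. TFPI2, an inhibitor of serine proteases, rose (log2 fold change 2.10, SE 0.25, adjusted p = 2.00e-04), and MMP7 rose from a day 10 level under that of the dim filter (log2 fold change 3.75, SE 0.43, adjusted p = 1.94e-04), at 2.03 with an offset.

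For fatty acid synthesis and lipid storage 0 of 16 measured members rose, 6 fell and 10 did not pass (0 up and 7 down adjusted over the list alone). The median over fatty acid synthesis and lipid storage was -0.24 (adjusted p = 0.00554, and adjusted p = 0.149 with an estimated correlation), with log2 fold changes of -0.73 for ACLY and -1.29 for LPIN1. For cholesterol synthesis 0 of 18 measured members rose, 6 fell and 12 did not pass (0 up and 6 down adjusted over the list alone). The median over cholesterol synthesis was -0.21 (adjusted p = 0.00786, and adjusted p = 0.417 with an estimated correlation), with -1.67 for INSIG1. That median was -0.118 with a stricter filter on dim probes, -0.389 with array weights, and -0.113 and -0.384 without CTC day 10 replicates 1 and 3. In the cell cycle list 5 of 36 measured members rose, 14 fell and 17 did not pass (6 up and 15 down adjusted over the list alone). Cell cycle genes had a median log2 fold change of -0.31 (adjusted p = 0.0458, and adjusted p = 0.708 with an estimated correlation), with -0.99 for TPX2 and 1.12 for CCNE2. That call ended without CTC day 10 replicate 1 (adjusted p = 0.0755), day 25 replicate 2 (0.0605) or replicate 3 (0.0633), with array weights (0.0565), a stricter filter on dim probes (0.0749), an offset (0.0519) or array background as a covariate (0.0501), without a trend (0.0594), and by fry (0.110). Among replication-dependent histones 1 of 15 measured members rose, 0 fell and 14 did not pass (1 up and 0 down adjusted over the list alone). Replication-dependent histones had a median log2 fold change of 0.47 (adjusted p = 0.00786, and adjusted p = 0.511 with an estimated correlation). That call ended without CTC day 10 replicate 3 (adjusted p = 0.0672) and by fry (0.0918).

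In all, 1736 probes rose and 1481 fell. The 3217 calls became 6613 with array weights, 1565 without CTC day 10 replicate 3, 2031 without CTC day 25 replicate 1 and 1530 without CTC day 25 replicate 3.

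Lesions of day 25 differed from those of day 10 at 12713 probes (5544 up, 7169 down), and each day 10 array was one of those with 49 to 54 dark probes. Of 9 reference genes 5 rose and 3 fell, with a median log2 fold change of 0.60 (adjusted p = 0.169). Lists of cell type markers moved on the same arrays: lung epithelial markers, which a lung cancer line may itself express, stood at 0.427 ± 0.103 on day 10 and -0.090 ± 0.113 on day 25. Leukocyte and red cell markers stood at 0.523 ± 0.287 and 0.124 ± 0.292 (SD, n = 3 each). SLC2A3 rose in lesions (log2 fold change 3.10, SE 0.27, adjusted p = 1.61e-07), as did P4HA1 (log2 fold change 3.13, SE 0.29, adjusted p = 2.81e-07), PFKFB4 (log2 fold change 2.14, SE 0.22, adjusted p = 8.56e-07) and FBN1 (log2 fold change 2.04, SE 0.21, adjusted p = 9.09e-07). CDC6 fell (log2 fold change -1.99, SE 0.17, adjusted p = 1.58e-07), as did ARHGAP11A (log2 fold change -2.75, SE 0.16, adjusted p = 4.20e-09), whose other probe was called lower too.

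In the hypoxia response list 17 of 24 measured members rose, 1 fell and 6 did not pass (19 up and 1 down adjusted over the list alone). Hypoxia response genes had a median log2 fold change of 1.10 (adjusted p = 6.69e-06, and adjusted p = 0.507 with an estimated correlation). In the cell cycle list 0 of 36 measured members rose, 29 fell and 7 did not pass (0 up and 29 down adjusted over the list alone). The median over cell cycle genes was -0.91 (adjusted p = 3.06e-06, and adjusted p = 0.507 with an estimated correlation), with log2 fold changes of -1.58 for MCM5 and -1.45 for MCM6. For cholesterol synthesis 11 of 18 measured members rose, 0 fell and 7 did not pass (11 up and 2 down adjusted over the list alone). Over cholesterol synthesis the median was 0.52 (adjusted p = 0.0107, and adjusted p = 0.507 with an estimated correlation), with 2.02 for MSMO1. For extracellular matrix 9 of 19 measured members rose, 3 fell and 7 did not pass (9 up and 3 down adjusted over the list alone). Matrix genes had a median log2 fold change of 0.27 (adjusted p = 0.0345, and adjusted p = 0.507 with an estimated correlation), with 1.71 for LAMA5 and 1.72 for HSPG2. That call ended without metastatic lesion day 10 replicate 3 (median 0.128, adjusted p = 0.0741) or day 25 replicate 3 (0.0544), with dark probes left out (0.0814), with array weights (0.0901) and with the mean over the probes of a gene (0.0623). Its median was 0.475 without metastatic lesion day 25 replicate 2 and 0.615 with a stricter filter on dim probes. Among ribosomal proteins 13 of 23 measured members rose, 3 fell and 7 did not pass (13 up and 4 down adjusted over the list alone). The median over ribosomal proteins was 0.23 (adjusted p = 0.0278, and adjusted p = 0.526 with an estimated correlation), but under quantile normalization the median was -0.01 and the call ended (adjusted p = 0.388), as it did without metastatic lesion day 25 replicate 1 (0.0583), without a trend (0.0521) and with the mean over the probes of a gene (0.0783).

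The change over time was compared between kinds of sample, over unlike intervals. It ran from day 2 to day 25 in primary tumour, and from day 10 to day 25 in CTC and lesions. The change in lesions rests on the day 10 arrays with the most dark probes and with a lower mean level of reference genes. In primary tumours and lesions, 1878 probes rose in both and 2523 fell in both, where independent lists would share 982 and 1331, and log2 fold changes correlated at 0.44 across probes, which are not independent replicates. Between primary tumour and CTC, changes in opposite directions exceeded those of independent lists: 614 probes rose in primary tumour and fell in CTC and 721 did the reverse, where 262 and 322 would by independent lists (correlation -0.18). In the same direction, 243 rose and 228 fell in both, where independent lists would share 308 and 275. Between CTC and lesions, 679 rose in CTC and fell in lesions and 499 did the reverse, against 560 and 370 by independent lists (correlation -0.14), while 329 rose and 458 fell in both, against 433 and 478. These pairs of comparisons share no arrays. In CTC over time, log2 fold changes of different probes of a gene correlated at only 0.104, so the overlaps with CTC are of probes and may not hold for genes.

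Lesions of day 10 differed from CTC of day 10 at 13202 probes, of which 7286 were higher and 5916 lower in lesions. There 13 of 19 matrix, 13 of 23 adhesion and 11 of 18 cholesterol synthesis genes were lower, and 1, 4 and 0 were higher, list calls that were lost with an estimated correlation (adjusted p = 0.219, 0.367 and 0.327). Reference genes moved with them: their mean level on day 10 lesion arrays was -0.416 ± 0.097, against 0.095 ± 0.099 in CTC of day 10 (SD, n = 3 each) and 0.008 to 0.190 as means of the other groups. Of 9 reference genes 5 were lower and 3 higher, with a median log2 fold change of -0.41 (adjusted p = 0.264, and adjusted p = 3.71e-05 by fry). FN1 was lower (log2 fold change -2.66, SE 0.21, adjusted p = 7.77e-08), as were TGFB1, a growth factor that induces matrix genes (log2 fold change -2.71, SE 0.21, adjusted p = 7.01e-08), and LOXL2, an enzyme that cross-links collagen (log2 fold change -1.88, SE 0.17, adjusted p = 3.87e-07). MSMO1, of cholesterol synthesis, was lower (log2 fold change -2.41, SE 0.26, adjusted p = 1.57e-06), and ZEB1, a repressor of epithelial genes, was higher (log2 fold change 1.96, SE 0.16, adjusted p = 1.19e-07).

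For extracellular matrix 1 of 19 measured members rose, 13 fell and 5 did not pass (1 up and 14 down adjusted over the list alone). The median over matrix genes was -0.75 (adjusted p = 0.00203, and adjusted p = 0.219 with an estimated correlation), with log2 fold changes of -2.02 for FBN1 and -1.67 for LAMA5. For cholesterol synthesis 0 of 18 measured members rose, 11 fell and 7 did not pass (0 up and 11 down adjusted over the list alone). Cholesterol synthesis had a median log2 fold change of -0.71 (adjusted p = 0.00438, and adjusted p = 0.327 with an estimated correlation), with -1.48 for LSS. Among immediate early genes 3 of 22 measured members rose, 15 fell and 4 did not pass (4 up and 16 down adjusted over the list alone). The median over immediate early genes was -0.75 (adjusted p = 0.00438, and adjusted p = 0.219 with an estimated correlation), with -1.85 for IER3. In the mesenchymal list 2 of 18 measured members rose, 11 fell and 5 did not pass (2 up and 11 down adjusted over the list alone). The median over mesenchymal state was -0.72 (adjusted p = 0.0173, and adjusted p = 0.219 with an estimated correlation), in which VIM had -0.81 (-0.34 under quantile normalization). For matrix proteolysis 2 of 23 measured members rose, 12 fell and 9 did not pass (2 up and 12 down adjusted over the list alone). Over matrix proteolysis the median was -0.42 (adjusted p = 0.0228, and adjusted p = 0.301 with an estimated correlation), with -1.92 for MMP14 and 1.23 for MMP3. That median was -0.263 without a filter on dim probes. For integrins and focal adhesion 4 of 23 measured members rose, 13 fell and 6 did not pass (4 up and 13 down adjusted over the list alone). The median over integrins and focal adhesion was -0.77 (adjusted p = 0.0228, and adjusted p = 0.367 with an estimated correlation), with -2.51 for ITGA7 and -1.32 for FLNA. With an offset that median was -0.346, and the values were 0.60 for MMP3 and -1.46 for ITGA7.

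For the heat shock response 1 of 13 measured members rose, 10 fell and 2 did not pass (1 up and 10 down adjusted over the list alone). The median over heat shock response was -0.60 (adjusted p = 0.0173, and adjusted p = 0.219 with an estimated correlation), with a log2 fold change of -1.48 for HSPB1. Among leukocyte and red cell markers 9 of 11 measured members rose, 0 fell and 2 did not pass (9 up and 0 down adjusted over the list alone). Leukocyte and red cell markers had a median log2 fold change of 0.92 (adjusted p = 0.0228, and adjusted p = 0.563 with an estimated correlation), with 1.53 for HBB, 0.92 for ITGAM and 1.18 for CD3D. With an offset that median was 0.537, and the values were 0.85 for HBB and 0.54 for ITGAM, while CD3D had 0.69 with array background as a covariate. Lung epithelial markers, which stood at 0.427 ± 0.103 against -0.032 ± 0.135 in CTC of day 10 (SD, n = 3 each), had 4 of 8 members higher and 0 lower, with a median log2 fold change of 0.35 (adjusted p = 0.340, and adjusted p = 1.16e-04 by fry). Of all 14061 tested genes, 4673 were higher in this comparison. Tested olfactory receptor probes at the same levels as the leukocyte markers in CTC of day 10 had a median log2 fold change of 0.48 in this comparison. The 6 largest falls by probe, IQCF1, RPL14, DHX16, TMEM165, SEMA4B and RIMKLB, were all at dark probes: mean log2 intensities on the 3 lesion arrays were 0 to 2.31 for the first 5, and 2.57 ± 3.34 for RIMKLB, whose other probe was called lower too (-3.54). With array background as a covariate the calls of matrix proteolysis (adjusted p = 0.0920), integrins (0.105, with a median of -0.465) and leukocyte markers (0.156) ended, and under quantile normalization that of the heat shock response did (0.0997). The leukocyte call also ended without a filter on dim probes (0.123) and with a stricter one (0.0669), and that of integrins with the mean over the probes of a gene (0.0825).

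Averaged over both days, lesions differed from CTC at 11850 probes (6163 up, 5687 down). Of 22 immediate early genes 16 were lower and 0 higher, and of 23 adhesion genes 12 were lower and 3 higher, list calls that were lost with an estimated correlation (adjusted p = 0.133 and 0.25). JUN was lower in lesions (log2 fold change -1.28, SE 0.07, adjusted p = 2.49e-09), as was FOS (log2 fold change -1.94, SE 0.15, adjusted p = 3.01e-07), and TNFRSF18, a receptor of the tumour necrosis factor family, was higher (log2 fold change 1.54, SE 0.15, adjusted p = 2.22e-06), at 0.95 with array background as a covariate. Among immediate early genes 0 of 22 measured members rose, 16 fell and 6 did not pass (1 up and 17 down adjusted over the list alone). Over immediate early genes the median was -0.75 (adjusted p = 1.39e-06, and adjusted p = 0.133 with an estimated correlation), with -1.20 for KLF6 and -1.49 for IER3. For integrins and focal adhesion 3 of 23 measured members rose, 12 fell and 8 did not pass (3 up and 12 down adjusted over the list alone). Over integrins and focal adhesion the median was -0.47 (adjusted p = 0.00644, and adjusted p = 0.25 with an estimated correlation), with -1.18 for ACTN4. That median was -0.224 with array background as a covariate. For extracellular matrix 2 of 19 measured members rose, 10 fell and 7 did not pass (2 up and 11 down adjusted over the list alone). Over matrix genes the median was -0.38 (adjusted p = 0.00644, and adjusted p = 0.256 with an estimated correlation), with -2.05 for COL1A1. For matrix proteolysis 3 of 23 measured members rose, 12 fell and 8 did not pass (3 up and 13 down adjusted over the list alone). Matrix proteolysis had a median log2 fold change of -0.38 (adjusted p = 0.0114, and adjusted p = 0.25 with an estimated correlation), with -1.14 for PLAUR. That median was -0.571 with array weights. In the mesenchymal list 2 of 18 measured members rose, 10 fell and 6 did not pass (2 up and 10 down adjusted over the list alone). Over mesenchymal state the median was -0.38 (adjusted p = 0.0186, and adjusted p = 0.206 with an estimated correlation), with -1.81 for TGFB1. For the heat shock response 1 of 13 measured members rose, 9 fell and 3 did not pass (1 up and 10 down adjusted over the list alone). Over heat shock response the median was -0.49 (adjusted p = 0.0122, and adjusted p = 0.133 with an estimated correlation), with -1.02 for HSPB1. Levels of immediate early genes differed more on day 25, at -0.397 in lesions and 0.389 in CTC, against -0.179 and 0.519 on day 10. Those of mesenchymal, heat shock and matrix genes differed more on day 10, when the mean level of reference genes was lower in lesions as well. Mesenchymal genes stood at -0.294 in lesions and 0.389 in CTC on day 10, against -0.025 and 0.151 on day 25. For heat shock genes these levels were -0.339 and 0.259 against 0.020 and 0.191, and for matrix genes -0.692 and 0.342 against -0.011 and 0.215. Among leukocyte and red cell markers 8 of 11 measured members rose, 0 fell and 3 did not pass (8 up and 0 down adjusted over the list alone). The median over leukocyte and red cell markers was 0.48 (adjusted p = 0.00884, and adjusted p = 0.485 with an estimated correlation). That call ended with array background as a covariate (median 0.186, adjusted p = 0.377), where the count of probes was 4574, and without a filter on dim probes (0.0941).

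**Figure D3:**
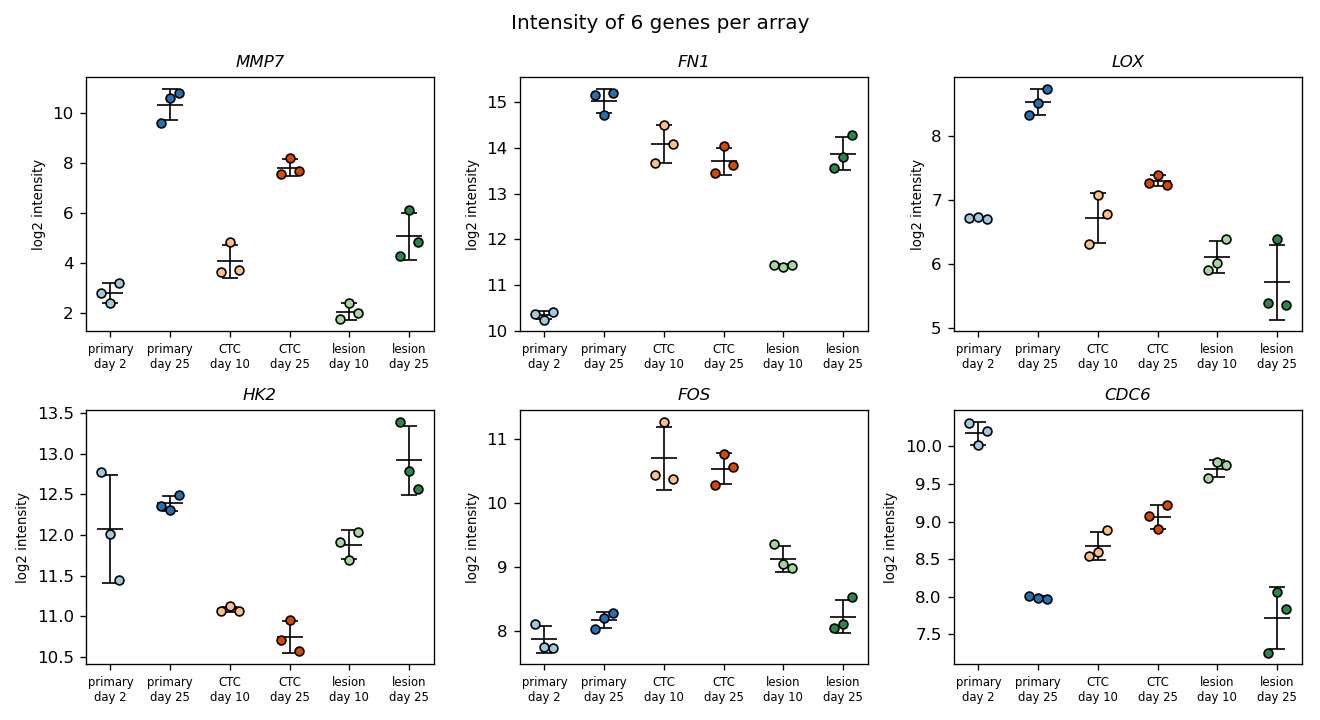
Log2 intensity of MMP7, FN1, LOX, HK2, FOS and CDC6 on each array, by group, with a bar at the group mean and its SD (n = 3). MMP7 lay at 10.34 ± 0.63 in primary tumour, 7.82 ± 0.34 in CTC and 5.08 ± 0.93 in lesions of day 25.

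Lists that were called in no comparison are given here for CTC against primary tumour at day 25. Among epithelial genes 1 rose and 1 fell of 13 (adjusted p = 0.735), among genes of the unfolded protein response 3 rose and 1 fell of 23 (adjusted p = 0.358), and among those of oxidative stress 3 rose and 0 fell of 17 (adjusted p = 0.52). Among apoptosis regulators 3 rose and 4 fell of 23 (adjusted p = 0.769), among inflammatory cytokines 5 rose and 2 fell of 18 (adjusted p = 0.206), and among stem cell associated genes 0 rose and 2 fell of 12 (adjusted p = 0.216). Among reference genes 1 rose and 1 fell of 9 (adjusted p = 0.739), among endothelial markers 1 rose and 0 fell of 8 (adjusted p = 0.861), and among lung epithelial markers 0 rose and 0 fell of 8 (adjusted p = 0.952).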

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

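The tests of the 3 patterns weighed here were chosen only after the results were seen, while the test of the change in the lesion against CTC difference was planned. The lesion against CTC difference changed between day 10 and day 25 at 10710 probes (4716 up, 5994 down), and the values below are that change on the log2 scale. The largest changes upward were RPL14 (7.56), IQCF1 (7.48), TMEM165 (7.19) and SEMA4B (7.05), all at dark probes, then PPP1R3G (6.79) and MGP (6.66). Downward they were WDR65 (-3.34), PPIF (-3.22), NRG1 (-3.12), GFRA3 (-3.11), ENTHD1 (-3.05) and GAST (-3.01). At PPP1R3G, MGP, WDR65, GFRA3, ENTHD1 and GAST at least 1 of the groups compared had a mean under the level of the dim filter, so the sizes and their order depend on background. With an offset the 6 upward changes and those of WDR65, GFRA3, ENTHD1 and GAST were smaller by over 1.5 times (2.64 for MGP and -1.51 for GAST). The call of GFRA3 ended with an offset on the linear scale (adjusted p = 0.0779) and with only the arrays compared (0.0542), and its value was larger by over 1.5 times with array weights and -1.64 without CTC day 25 replicate 2.

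Of 29 lists, 6 changed between days. Reference genes moved in the same contrast, with 5 of 9 up, 3 down and a median of 0.735 (adjusted p = 0.167, and adjusted p = 1.67e-04 by fry), a size over the medians of matrix, cell cycle, fatty acid and ribosomal genes below. In the hypoxia response list 14 of 24 measured members rose, 2 fell and 8 did not pass (15 up and 2 down adjusted over the list alone). The median over hypoxia response genes was 1.12 (adjusted p = 4.53e-04, and adjusted p = 0.43 with an estimated correlation). For cholesterol synthesis 11 of 18 measured members rose, 0 fell and 7 did not pass (11 up and 0 down adjusted over the list alone). The median over cholesterol synthesis was 1.19 (adjusted p = 0.00109, and adjusted p = 0.43 with an estimated correlation). For fatty acid synthesis and lipid storage 10 of 16 measured members rose, 3 fell and 3 did not pass (10 up and 3 down adjusted over the list alone). Over fatty acid synthesis and lipid storage the median was 0.71 (adjusted p = 0.0216, and adjusted p = 0.43 with an estimated correlation), led by SCD (log2 fold change 3.94, SE 0.26, adjusted p = 5.19e-08), a call that ended with the mean over the probes of a gene (adjusted p = 0.0536). For extracellular matrix 7 of 19 measured members rose, 1 fell and 11 did not pass (7 up and 1 down adjusted over the list alone). Matrix genes had a median log2 fold change of 0.47 (adjusted p = 0.0216, and adjusted p = 0.43 with an estimated correlation), a call that ended with dark probes left out (adjusted p = 0.0540) and whose median was 0.262 with an offset and 0.309 without metastatic lesion day 25 replicate 3. In the cell cycle list 0 of 36 measured members rose, 15 fell and 21 did not pass (0 up and 15 down adjusted over the list alone). Over cell cycle genes the median was -0.47 (adjusted p = 0.00821, and adjusted p = 0.58 with an estimated correlation), at -0.734 with array weights. Among ribosomal proteins 10 of 23 measured members rose, 2 fell and 11 did not pass (10 up and 2 down adjusted over the list alone). Over ribosomal proteins the median was 0.21 (adjusted p = 0.0478, and adjusted p = 0.588 with an estimated correlation), but the median was 0 under quantile normalization, where the call ended (adjusted p = 0.560). It also ended without a filter on dim probes (0.0574), without a trend (0.107), with dark probes left out (0.0517), array background as a covariate (0.0837) or the mean over the probes of a gene (0.0904). So it did without CTC day 10 replicate 1 (0.0866), CTC day 25 replicate 3 (0.0798), metastatic lesion day 10 replicate 1 (0.0865), metastatic lesion day 25 replicate 1 (0.0940) or replicate 2 (0.0676).

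Probes more than 8-fold lower in lesions than in CTC at day 10 numbered 211 with 1 symbol. Of these, 61 had another probe of the gene that was bright in CTC, and the median fall of those other probes was 0.104 of the fall of the probe itself (95% bootstrap interval 0.0373 to 0.141), as signal lost at single probes would give. Since the probes were chosen for their own large fall, selection alone would also give a ratio under 1. In primary tumour the ratio for rises over 8-fold was 0.356 over 9 probes chosen in the same way. Lower transcript levels stay open for part of the genes, since 42.9% of the other probes (30 of 70, binomial interval 31.1% to 55.3%) were called lower, though so were 5916 of all 22218 tested probes. Signal loss at single probes may account for part of the size of these falls, but it was not separated from the effect of selection. The labels name nothing that separates it from the group.

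Leukocyte and red cell markers rose in day 10 lesions by a median of 0.92 on the log2 scale against CTC (adjusted p = 0.0228, and adjusted p = 0.563 with an estimated correlation), in a culture seeded with a tumour cell line. Of 8 lung epithelial markers 4 rose as well (median 0.35, adjusted p = 0.340), as did 4673 of all 14061 tested genes, and the line is itself from lung. Olfactory receptor probes at the levels of the leukocyte markers, 75 in number, had a median of 0.48 (SE 0.06, 34 called higher and 13 lower), so raised background could account for part of the rise but was not shown to give all of it. Like the markers, these probes had passed the dim filter, and they were matched by level in CTC of day 10. That selection may have raised their median. CD74 and HLA-DRA, abundant in antigen-presenting leukocytes, had log2 fold changes of -0.22 (SE 0.29) and 0.03 (SE 0.41), with upper bounds of at most 0.85 at 2 SE. Both are members of the list and the only ones that did not pass, so the median they are set against includes them. CD74 lay under the list's median by 1.14, more than 2 SE of that difference (0.685), but HLA-DRA by 0.882 did not (1.45). That bound was widened by the list's own spread after its first result was seen, so this test cannot decide on leukocytes. Per the labels H1299 cells were seeded into decellularized rat lungs, and no human leukocytes are named as added.

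Hypoxia response genes had a median of -0.94 in CTC against primary tumour and 0.95 in lesions against CTC at day 25, calls that were lost with an estimated correlation (adjusted p = 0.249 and 0.508). With array background as a covariate, the median was -0.93 against primary tumour (adjusted p = 4.94e-10 at the preset correlation) and 1.01 for lesions against CTC (adjusted p = 6.30e-06), so differences in background were not the whole cause. A hypothesis is that oxygen becomes limiting as solid samples grow: the list rose over time in primary tumour (median 0.86) and in lesions (1.10), calls also lost with an estimated correlation (adjusted p = 0.263 and 0.507), and in CTC its median was -0.13. The mean level of reference genes moved the same way in lesions, from -0.416 on day 10 to 0.114 on day 25, so the lesion rise may in part be a shift of the day 10 arrays. Single reference genes moved both ways, and GAPDH and PGK1 are also in the glycolysis list, so such a shift was not established. The interval began on day 2 in primary tumour and on day 10 in lesions and CTC. No sample was measured for oxygen, and handling of cells taken from medium, which the design confounds with the group, was not tested.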

How the results depend on the processing

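Tests chosen only after the data were seen were dark probes left out, the fit without day 10 lesions, the background covariate and leave-one-out for the lists. No call reversed in direction by its own test. Of 378 named gene results, 377 kept their call with array weights, 352 with the background covariate, 360 with only the arrays compared, 370 without a filter and 376 under quantile normalization, and of 2796 leave-one-out values 91 lost it. Of 59 list calls, 55 held with array weights, 50 with the background covariate, 55 under quantile normalization, 57 by fry and 3 with an estimated correlation. Of 432 leave-one-out list values 28 lost the call. The causes were not tested, except that fewer arrays give fewer degrees of freedom.

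Array weights gave 9186 probes for CTC against primary tumour, 10342 for lesion against primary tumour, 13386 for lesion against CTC at day 25, 6613 for CTC over time and 5483 apart in CTC (53.6% higher in CTC against 65.9%). The background covariate gave 3826 for lesion against CTC at day 25, 4574 averaged and 1023 apart in CTC. Only the arrays compared gave 1935 for lesion against primary tumour, 3131 for lesion against CTC at day 25 and 1045 apart in CTC.

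Leaving out 1 array gave 1784 to 2345 for CTC against primary tumour, 3143 to 6295 for lesion against primary tumour, 4472 to 9161 for lesion against CTC at day 25, 1530 to 2760 for CTC over time and 892 to 2321 apart in CTC. Ranges for the others were 11472 to 12791 for lesion against CTC at day 10, 6647 to 7310 for primary tumour, 11365 to 12711 for lesions over time, 10502 to 13055 averaged, 9461 to 11036 for the change of the difference and 17641 to 19520 for any difference.

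Replicate numbers were not shown to pair the arrays: of 45 pairs with the same number 19 had deviations correlated above 0.1 (range -0.324 to 0.428), and 7 of 18 arrays matched their own number best. The median correlation was 0.070 for the same number and -0.026 for other numbers. No chance level was computed for these values. With the number as a block, of the list calls that of ribosomal proteins in the change of the difference ended (adjusted p = 0.0567). Every count of probes was higher with the block, none by over 1.5 times, so some variation shared by number is not excluded. These counts were 3371 for CTC against primary tumour, 5542 for lesion against primary tumour, 7839 for lesion against CTC at day 25 and 13409 at day 10. Over time they were 8336 for primary tumour, 3470 for CTC and 13014 for lesions. The averaged difference gave 12077, its change between days 10975, probes apart in CTC 1757 and any difference 18776.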

Other observations

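The test of array background within groups was chosen only after the data were seen, while the counts over other splits were planned. Within groups, the first axis of variation held 32.1% of the variance and followed the olfactory receptor median over 18 arrays (Pearson r = 0.872, permutation p = 3.00e-05, Spearman rho = 0.808, permutation p = 1.40e-04, 100000 resamples, and r = 0.773 without the 2 arrays farthest from the median). It was the 1 such relation computed. Axis and median were both deviations from group means, and the permutations shuffled arrays across groups without keeping this, so the p-values may be too small. Olfactory receptor probes that passed the filter were also among those from which the axis was taken.

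Different probes of a gene were compared over 3591 genes with several tested probes. Their log2 fold changes correlated, across genes that are not independent replicates, at 0.604 in primary tumour over time and 0.501 for CTC against primary tumour, but at 0.175 for lesion against CTC at day 10, 0.252 for lesions over time and 0.104 for CTC over time.

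Splits of the arrays into other groups were counted. A split that mixes groups adds their difference to the pooled spread, which lowers its count, so low counts in mixed splits were to be foreseen. In each of the 7 pairwise comparisons, 1 of the 10 splits, the real one, gave as many probes, and 10 splits are too few for a share under 0.05. The highest count in another split was 1 against 3225 for CTC against primary tumour, 2 against 5110 for lesion against primary tumour, 0 against 7397 for lesion against CTC at day 25, 1 against 13202 at day 10, 0 against 8061 for primary tumour over time, 0 against 3217 for CTC and 1 against 12713 for lesions. For the lesion against CTC average 1 of 100 splits, the real one, gave as many (11850, highest other 10840). For any difference among groups it was 1 of 100 as well (18607, highest other 4146). Both shares were under the 0.05 set beforehand. The splits treat arrays as independent, and the labels do not say whether those of a group came from separate models, so chance is not excluded. Splits that kept the day 10 groups gave 6138 to 10840 for the average, and those that kept only the day 25 groups 293 to 1436. Mixing the groups of a day widens the spread for both days, so these counts do not give the share of each day. For the change between days 2 of 100 splits gave as many (10710, highest other 10840), with 5879 to 10840 where the day 10 groups were kept. Splits within a day remove the lesion against CTC difference itself, so they do not test whether it changed, and the share expected beforehand to exclude chance decides nothing here. For probes apart in CTC, 3 of 100 splits gave as many (1652), the real one, one with 3038 in which lesions took the place of CTC, and one with 2562 in which the groups were mixed, so counts above the real one do not need CTC as the group apart.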
